A study of Mus musculus with 2 samples.

How the data were processed

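RNA was sequenced from 2 libraries of pancreatic islet beta cells of mutant mice. Per the labels, islets were dissociated with trypsin at body temperature, the cells were purified by fluorescence-activated cell sorting, and total RNA was extracted with a column kit. Libraries were built with Illumina TruSeq DNA kits, which do not mark strand, and the labels give the sex as pooled males and females. The genotype label names floxed alleles of Myt1, Myt2 and Myt3 together with RipCre, a Cre recombinase under the rat insulin promoter. Myt2 and Myt3 are also known as Myt1l and St18, the symbols that the files use. Both libraries formed 1 group. The label of library 2 calls it a duplicate and does not say whether it came from other mice. A p-value therefore measures only the reads of these libraries or the spread between them, which by the labels alone may be technical. For the genes they cover, the values argue against 2 libraries of the same RNA. All 4 Y-linked genes were lower in library 2 (median log2 ratio −0.78). All 24 tested of 25 genes induced by interferon gamma were higher in it (median 1.0). Whether other mice or only other cells were used stays unknown. Control beta cells were not analysed here, so nothing in the values compares mutant with control cells.

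The deposited tables list 55487 genes, each with a raw read count, a length-scaled TPM value and a CPM value, per the file headers. The submitters' processing notes name cutadapt 2.10, STAR 2.7.8a, featureCounts 2.0.2 and the build GRCm38.p6. Their parameters, the strand setting and the handling of reads that match several places are not given in the sources used here. The deposited CPM equals the raw count divided by the library total, scaled to a common total, with a largest difference of 1.8e-12. The deposited TPM value scales each count by a gene length. This length was checked in library 1 only, over 16229 genes with more than 20 reads. In 98.35% of them, the length that TPM implies, scaled to the median over genes, lay within 1% of the merged exons in GENCODE M21. Of the 55487 identifiers, 55227 were found in that annotation, which gave coordinates, strand and biotype on GRCm38. A total of 109 symbols had more than 1 identifier, and the identifier with most reads kept the symbol.

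Library 1 held 50121771 counted reads and library 2 held 39003197. The limit that a count of 0 allows, 3 reads, was 0.0599 CPM in library 1 and 0.0769 CPM in library 2. Intervals at 95% are exact Clopper-Pearson binomial intervals of a gene's share of the counted reads. Intervals and limits cover counting error only, because reads without molecular identifiers are not independent molecules. Means are given with the SD of the 2 libraries (n = 2).

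Agreement of the libraries was measured over the 20681 genes with 10 or more reads summed. The measures were a chi-square test of homogeneity of the counts, edgeR's common dispersion with an intercept only, and Pearson and Spearman correlations across genes of log2(CPM + 1). Genes are not independent replicates, so those correlations describe the libraries. Each gene was then tested with an exact two-sided binomial test against the libraries' totals, with Benjamini-Hochberg adjustment over the 20681 genes. A gene was called where the adjusted p was under 0.05 and the CPM ratio, with 0.5 read added, was 2-fold or more. This test compares the reads of the 2 libraries, not conditions. A test with replicate spread between groups needs a second group, so edgeR's quasi-likelihood test was not run.

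There were 32 gene lists of 412 genes, 22 for cell programs and 10 for markers of other cell types. The program lists covered the targeted genes, hormones, beta-cell transcription factors, beta-cell maturation, secretory granules, exocytosis, genes disallowed in beta cells, the unfolded protein response, the ATF4 response, heat shock, antioxidant defence, immediate-early genes, proliferation, cell-cycle inhibitors, D cyclins with their kinases, progenitors, neurons, glycolysis, the TCA cycle with anaplerosis, mitochondrially encoded genes, apoptosis and sex-linked genes. The marker lists covered alpha, delta, PP, acinar, ductal, endothelial, mesenchymal, immune, Schwann or glial, and erythroid cells. A list's level was the median of log2(TPM + 1) over its members. It was given as a percentile among 10000 random lists of the same size, drawn from the 13955 genes with a mean of 1 CPM or more. A member was detected at 1 CPM or more in both libraries. Members under 1 CPM stayed in the median of their list, so where few members reach it, the percentile is low by construction. The difference of a list between the libraries was the median log2 ratio of library 2 over library 1, given as a percentile among 10000 random lists matched on mean expression, each member being replaced by 1 of its 200 nearest genes. These percentiles describe the libraries and are not p-values. For 18 fixed gene pairs, the ratio of length-scaled values was computed in each library with an exact binomial interval. It was tested with an exact two-sided binomial test against equal values, with adjustment over 36 tests, and a pair was called where both libraries passed in the same direction.

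The genes named are the targeted genes, the hormones, the 10 genes with the highest mean CPM, the 3 highest members and the lowest detected member of each list, both genes of each pair, and the 5 genes with the largest ratio in each direction among called genes with a mean of 10 CPM or more. List members called different between the libraries, and a few further members, are named as well and were chosen after their values were seen. Some genes and pairs that this rule names are not reported here. The lists, the pairs, the tests and all alternatives but 1 were fixed before the data were examined. The alternatives were other library scalings (edgeR's TMM, DESeq2 size factors, totals without the 10 highest genes or without mitochondrial genes), other minimums of summed reads (1 and 100), no minimum ratio, other detection limits (0.5 and 5 CPM), random lists of protein-coding genes, values without length scaling, and leaving out each library. The alternative chosen after seeing the data was edgeR's exact negative binomial test with the common dispersion of the 2 libraries taken as 1 group.

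To find reads that could belong to near-identical copies, the transcripts of each named gene were broken into words of 50 bases, and the share of words also present in transcripts of other genes was counted. Overlap of merged exons with other genes on either strand was measured from the annotation. The steps were tested on simulated counts with the real means and totals and with counting error alone. Spread between the libraries beyond counting error was not simulated, so the rates below do not cover it. For library 2 against library 1, the gene test recovered 99.5% of 200 genes changed 3-fold among 20737 genes and called 0 unchanged genes. Of 200 unchanged lists, 6.0% lay outside the central 95% of random lists, and 100% of 50 lists shifted by 0.3 on the log2 scale were found. Of 500 simulated pair intervals, 97.0% held the true ratio. The work used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.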

Results

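Beta cells are the insulin-secreting cells of the pancreatic islet. The study asked which genes depend on the Myt family of zinc-finger transcription factors in these cells when blood glucose is normal. Transcriptomes were measured by RNA sequencing of sorted beta cells from mice 2 months old in which Myt1, Myt1l and St18 carried floxed alleles together with RipCre. The 2 libraries, both of mutant cells, held 50121771 and 39003197 counted reads. In library 1, 32026 genes had at least 1 read and 13995 reached 1 CPM. In library 2 the numbers were 30732 and 13834. Reads of protein-coding genes made up 97.75% and 97.66% of the totals, and mitochondrial genes made up 1.78% and 2.01%.

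Transcripts of all 3 targeted genes were counted in both libraries. Myt1 stood at 77.6 CPM in library 1 and 65.4 CPM in library 2, a mean of 71.5 ± 8.63 CPM (SD, n = 2). St18 stood at 72.7 and 56.5 CPM, a mean of 64.6 ± 11.5 CPM (SD, n = 2). Myt1l was lowest, at 44.5 and 39.0 CPM, a mean of 41.8 ± 3.85 CPM (SD, n = 2). The exact 95% binomial intervals in library 1 were 75.2 to 80.1 CPM for Myt1, 70.4 to 75.1 CPM for St18 and 42.7 to 46.4 CPM for Myt1l. Scaled by length, the 3 genes had a median of 27.1 TPM, at percentile 77.28 of random lists of the same size. Within the libraries, length-scaled Myt1 exceeded Myt1l 3.33-fold (mean log2 ratio 1.74 ± 0.04, SD, n = 2) and St18 exceeded Myt1l 3.33-fold (1.74 ± 0.12). Both differences passed the exact binomial test in both libraries. Without length scaling the mean log2 ratios were smaller, at 0.77 for Myt1 over Myt1l and 0.62 for St18 over Myt1l. The difference between Myt1 and St18 did not pass it, with ratios of Myt1 over St18 of 0.96 (95% interval 0.917 to 1.0) in library 1 and 1.04 (0.983 to 1.10) in library 2. Without length scaling it passed, at a mean log2 ratio of 0.15. Myt1 (ENSMUSG00000010505) lies on chromosome 2 from 181763332 to 181827797 on the plus strand, with 25 merged exons (GRCm38, GENCODE M21). Myt1l (ENSMUSG00000061911) lies on chromosome 12 from 29528384 to 29923213 with 30 merged exons, and St18 (ENSMUSG00000033740) on chromosome 1 from 6487231 to 6860940 with 29, both on the plus strand. The counts sum all exons of a gene, so they cannot separate exons inside a deleted part from exons that remain, and these levels do not check the deletion.

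The insulin genes dominated the transcriptome. Ins2 took 10.4% of the reads in library 1 and 11.1% in library 2, and Ins1 took 5.745% and 5.332%. Iapp, which encodes the co-secreted peptide amylin, took 1.31% and 1.37%. The exact 95% binomial intervals were 10.37% to 10.39% and 11.08% to 11.10% for Ins2, and 5.738% to 5.751% and 5.325% to 5.339% for Ins1. Hormones of other islet cells were counted at far lower levels. Somatostatin (Sst) had a mean of 1307 ± 293 CPM (SD, n = 2), pancreatic polypeptide (Ppy) 755 ± 175 CPM, glucagon (Gcg) 396 ± 92.9 CPM and peptide YY (Pyy) 338 ± 8.0 CPM. Ghrelin (Ghrl) was not detected at 1 CPM, with 0.339 and 0.154 CPM. The 8 hormones had a median of 4470 TPM, at percentile 100 of random lists. The remaining genes among the 10 highest were the granule genes Chgb, Chga, Scg2 and Cpe, the mitochondrial genes mt-Co1 and mt-Cytb, and G6pc2, the islet glucose-6-phosphatase. Together the 10 took 22.1% and 22.45% of the reads. Length-scaled Ins2 exceeded Ins1 1.57-fold (mean log2 ratio 0.65 ± 0.14, SD, n = 2). Ins1 (ENSMUSG00000035804) lies on chromosome 19 from 52264297 to 52265476, and Ins2 (ENSMUSG00000000215) on chromosome 7 from 142678656 to 142743381 on the minus strand. The insulin genes shared 0.7% and 0.5% of their 50-base words with other genes.

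**Figure D1:**
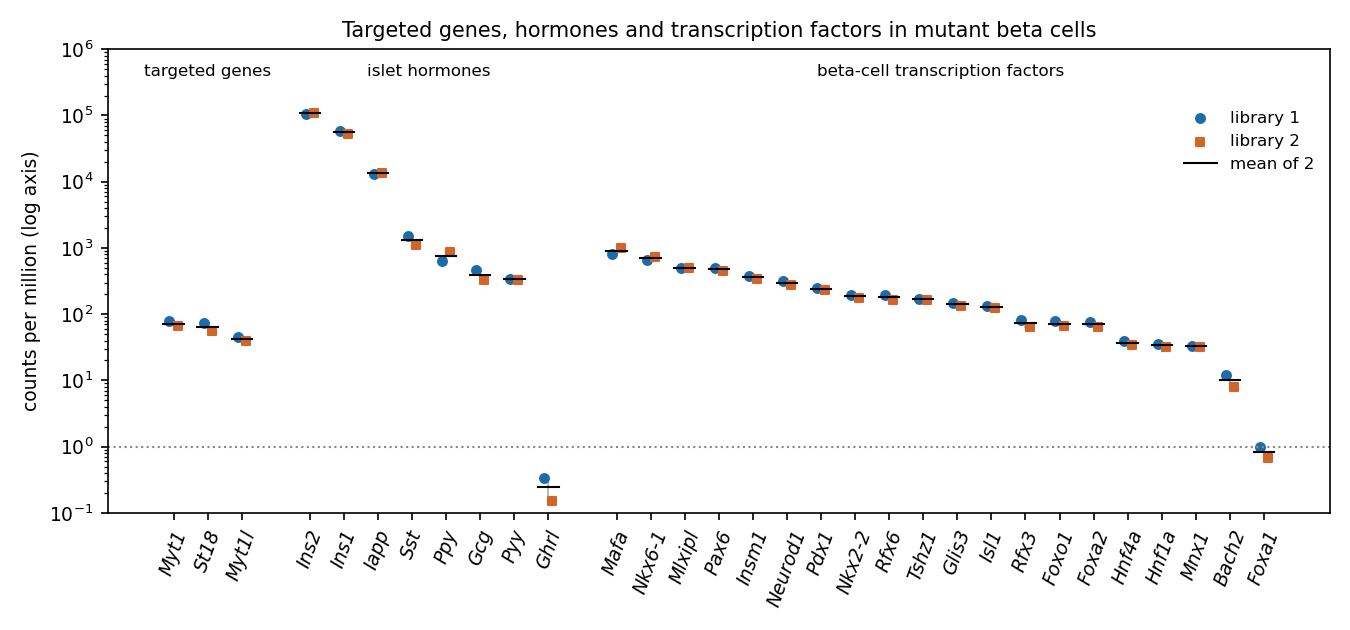
CPM (log axis) of the targeted genes, the islet hormones and the beta-cell transcription factors in library 1 (circles) and library 2 (squares) of mutant beta cells, with the mean of the 2 libraries as a bar and a dotted line at 1 CPM. Myt1, St18 and Myt1l lie between 39.0 and 77.6 CPM, and Ghrl and Foxa1 lie below 1 CPM in both libraries.

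Genes that mark the identity of beta cells were expressed as a group. Of 20 beta-cell transcription factors, 19 were detected in both libraries, with a median of 84.2 TPM at percentile 100. Mafa, an activator of insulin transcription, had a mean of 902.5 ± 130 CPM (SD, n = 2), and Nkx6-1 had 696 ± 39.9 CPM. Insm1 had 359 ± 32.6 CPM and Pdx1 had 240 ± 10.5 CPM. The lowest detected member was Bach2 at 10.01 ± 2.84 CPM, and Foxa1 was under 1 CPM with 0.978 and 0.667 CPM. All 23 genes of beta-cell maturation and glucose sensing were detected, with a median of 356 TPM at percentile 100. Behind the insulins and Iapp stood G6pc2 at 3401 ± 394 CPM, Glp1r at 1448 ± 186 CPM and the glucose transporter Slc2a2 at 758.5 ± 179 CPM. Urocortin 3 (Ucn3), a peptide of mature beta cells, had 267 ± 41.4 CPM, and the lowest detected member by TPM was the calcium channel Cacna1c at 106 ± 12.9 CPM. Length-scaled Gcg exceeded Ucn3 1.46-fold, with 1.92-fold in library 1 and 1.10-fold in library 2. The incretin receptor Glp1r exceeded Gipr 7.59-fold, and G6pc2 exceeded G6pc3 117-fold.

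The secretory machinery was abundant. All 16 secretory granule genes were detected, with a median of 665 TPM at percentile 100, led by Chgb at 12620 ± 2978 CPM, Chga at 10420 ± 1282 CPM and Scg2 at 6813 ± 686 CPM (SD, n = 2). The lowest was the monoamine transporter Slc18a1 at 18.34 ± 0.967 CPM. Of 17 exocytosis genes, 15 were detected, with a median of 106 TPM at percentile 100. By TPM, Syt13, Cplx2 and Rab3d led this list, with 1475 ± 141, 532 ± 66.5 and 360.5 ± 19.3 CPM, and Exoc1 was the lowest detected member by TPM at 33.3 ± 3.24 CPM. Doc2b, at 0.938 and 1.26 CPM, did not reach the detection limit in both libraries, and the SNARE gene Stx1a had 13.3 ± 1.87 CPM. The prohormone convertase pair was close, with Pcsk1 over Pcsk2 at 1.13-fold in each library, and without length scaling the order turned to a log2 ratio of −0.32.

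Stress-response and immediate-early genes were expressed at high levels in these cells, which had been dissociated with trypsin at body temperature and sorted. No cells handled otherwise were analysed, so any effect of that handling on the levels cannot be told apart. All 22 genes of the unfolded protein response were detected, with a median of 370 TPM at percentile 100. The endoplasmic reticulum chaperone Hspa5 had a mean of 2847 ± 194 CPM (SD, n = 2), Calr had 1335 ± 104 CPM and Pdia3 had 1198 ± 75.5 CPM, and the lowest member was the stress kinase gene Eif2ak3 at 96.4 ± 7.89 CPM. Hspa5 exceeded its cytosolic relative Hspa8 6.63-fold, but 39.4% of the words of Hspa8 occur in other genes, so its count is uncertain. All 17 genes of the ATF4 response were detected, with a median of 74.3 TPM at percentile 100. By TPM, Atf3 led with 779.5 ± 140 CPM, followed by Atf4 with 390 ± 31.4 CPM and Ppp1r15a with 397 ± 8.44 CPM, and Slc7a11 was the lowest by TPM at 15.3 ± 3.79 CPM. Atf4 exceeded Ddit3, which encodes CHOP, 2.16-fold. All 15 immediate-early genes were detected, with a median of 515 TPM at percentile 100. Fos had 2471 ± 26.8 CPM, Jun 1900 ± 30.7 CPM and Btg2 1559 ± 116.5 CPM, and the lowest by TPM was Ier3 at 4.68 ± 0.0158 CPM. Jund shares 48.3% of its words with an antisense gene over which 52.6% of its exons lie, so its count is uncertain.

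Heat-shock and antioxidant genes also lay above most genes, with the same limit on the handling of the cells. Of 18 heat-shock genes, 17 were detected, with a median of 88.6 TPM at percentile 100. Hsp90ab1 had 1054 ± 10.25 CPM (SD, n = 2) and Dnajb1 had 334 ± 41.3 CPM. The copies Hspa1a and Hspa1b share 66.3% and 62.3% of their words, so their counts, with means of 145 and 344 CPM, are uncertain. Hspa4l was the lowest detected member by TPM at 46.8 ± 2.60 CPM, and Cryab was not detected, at 0.359 and 0.231 CPM. All 20 antioxidant genes were detected, with a median of 58.7 TPM at percentile 100. Gpx3 had 1966 ± 32.2 CPM, Txnip, a glucose-responsive inhibitor of thioredoxin, had 1508 ± 376 CPM, Txn1 had 48.8 ± 1.86 CPM, and Gpx7 was the lowest detected member by TPM at 1.37 ± 0.0519 CPM.

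Glucose metabolism showed high expression of mitochondrial genes and low expression of most genes known as disallowed in beta cells. All 19 genes of the TCA cycle and anaplerosis were detected, with a median of 68.3 TPM at percentile 100, led by TPM by Mdh1 at 285 ± 7.45 CPM, Ogdh at 325 ± 15.85 CPM and Sdha at 205 ± 1.26 CPM (SD, n = 2), with Me3 the lowest by TPM at 10.5 ± 2.57 CPM. Pyruvate carboxylase (Pcx) exceeded Pck2 2.40-fold. Of 19 glycolytic genes, 17 were detected, with a median of 35.9 TPM at percentile 99.44. This became percentile 93.88 without length scaling and 96.92 with detection at 5 CPM. Pkm and Aldoa were among the highest members, with 568 ± 40.4 and 257 ± 25 CPM, and Ldha was the lowest detected member by TPM at 1.77 ± 0.259 CPM. Hexokinase 1 (Hk1) was not detected, with 0.978 and 0.564 CPM. Ldhb exceeded Ldha 7.90-fold, and the glucose transporter Slc2a2 exceeded Slc2a1 33.6-fold, with 51.9-fold in library 1 and 21.7-fold in library 2. Of 23 disallowed genes, 16 were detected, with a median of 2.40 TPM at percentile 0. The monocarboxylate transporter Slc16a1 had 0.259 and 0.231 CPM. Among the highest members were Dapp1 at 54.6 ± 14.1 CPM and Mgst1 at 25.5 ± 5.74 CPM. The lowest detected member by TPM was Rest, the repressor of neuronal genes, at 1.93 ± 0.134 CPM. Of the 13 mitochondrially encoded genes, 7 were detected, with a list median of 2770 TPM at percentile 100. These included mt-Co1 at 5715 ± 544 CPM, mt-Cytb at 4206 ± 287 CPM, mt-Nd1 at 2118 ± 141 CPM and mt-Nd4 at 1394 ± 108 CPM. The other 6 lay under 1 CPM. Of these, mt-Nd3, mt-Nd4l, mt-Co2, mt-Co3 and mt-Atp6 share nearly all of their words with nuclear copies and their counts are uncertain.

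Most genes of the proliferation and progenitor lists were low. Of 19 proliferation genes, 13 were detected, with a median of 1.78 TPM at percentile 0. Pcna had 38.9 ± 7.40 CPM, Mcm2 had 31.9 ± 3.36 CPM and Mki67 had 7.40 ± 0.527 CPM (SD, n = 2). Aurka had 5.07 ± 1.02 CPM, and the lowest detected member by TPM was Cdk1 at 1.41 ± 0.115 CPM. Among D cyclins and their kinases, 4 of 5 were detected, with a median of 12.4 TPM at percentile 43.24. Ccnd2 had 991 ± 20.6 CPM, Cdk4 had 117.5 ± 3.49 CPM, Ccnd3 had 39.9 ± 4.54 CPM and Cdk6 was not detected. Ccnd2 exceeded Ccnd1, which had 11.8 ± 4.94 CPM, 43.9-fold, with 58.7-fold in library 1 and 32.9-fold in library 2. All 10 cell-cycle inhibitors were detected, with a median of 20.3 TPM at percentile 77.92. Cdkn1b had 101 ± 1.33 CPM, Men1 had 72.4 ± 2.34 CPM, Cdkn1a had 53.95 ± 25.5 CPM and Cdkn1c was lowest at 1.26 ± 0.222 CPM. Cdkn1b exceeded Cdkn1a 2.21-fold in library 1 and 1.08-fold in library 2. Of 12 progenitor genes, 5 were detected, with a median of 0.999 TPM at percentile 0, which so few detected members give by construction. The highest members by TPM were Hes1 with 40.0 ± 8.56 CPM, Neurog3, the endocrine progenitor factor, with 16.0 ± 8.35 CPM, and Aldh1a3 with 10.2 ± 1.08 CPM. Sox2, Pou5f1 and Ptf1a had at most 0.103 CPM in either library.

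Neuronal genes were partly shared with these endocrine cells. Of 16 neuronal genes, 12 were detected, with a median of 28.3 TPM at percentile 96.17. Celf3 had 378 ± 22.1 CPM, Syp had 227.5 ± 21.2 CPM and Tubb3 had 56.7 ± 14.3 CPM (SD, n = 2). Rbfox3, Elavl3, Nefl and Stmn2 were not detected in both libraries. Library 1 alone gave percentile 97.95 for this list. Of 15 apoptosis genes, 13 were detected, with a median of 15.1 TPM at percentile 55.71. Mcl1 had 157 ± 10.5 CPM, Bax had 19.9 ± 0.211 CPM, Bbc3 had 19.5 ± 2.87 CPM and Apaf1 was the lowest detected member by TPM at 10.7 ± 1.20 CPM. Bcl2 and Pmaip1 were under 1 CPM in both libraries. The 6 sex-linked genes had a median of 13.9 TPM at percentile 50.29, and 5 were detected.

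**Figure D2:**
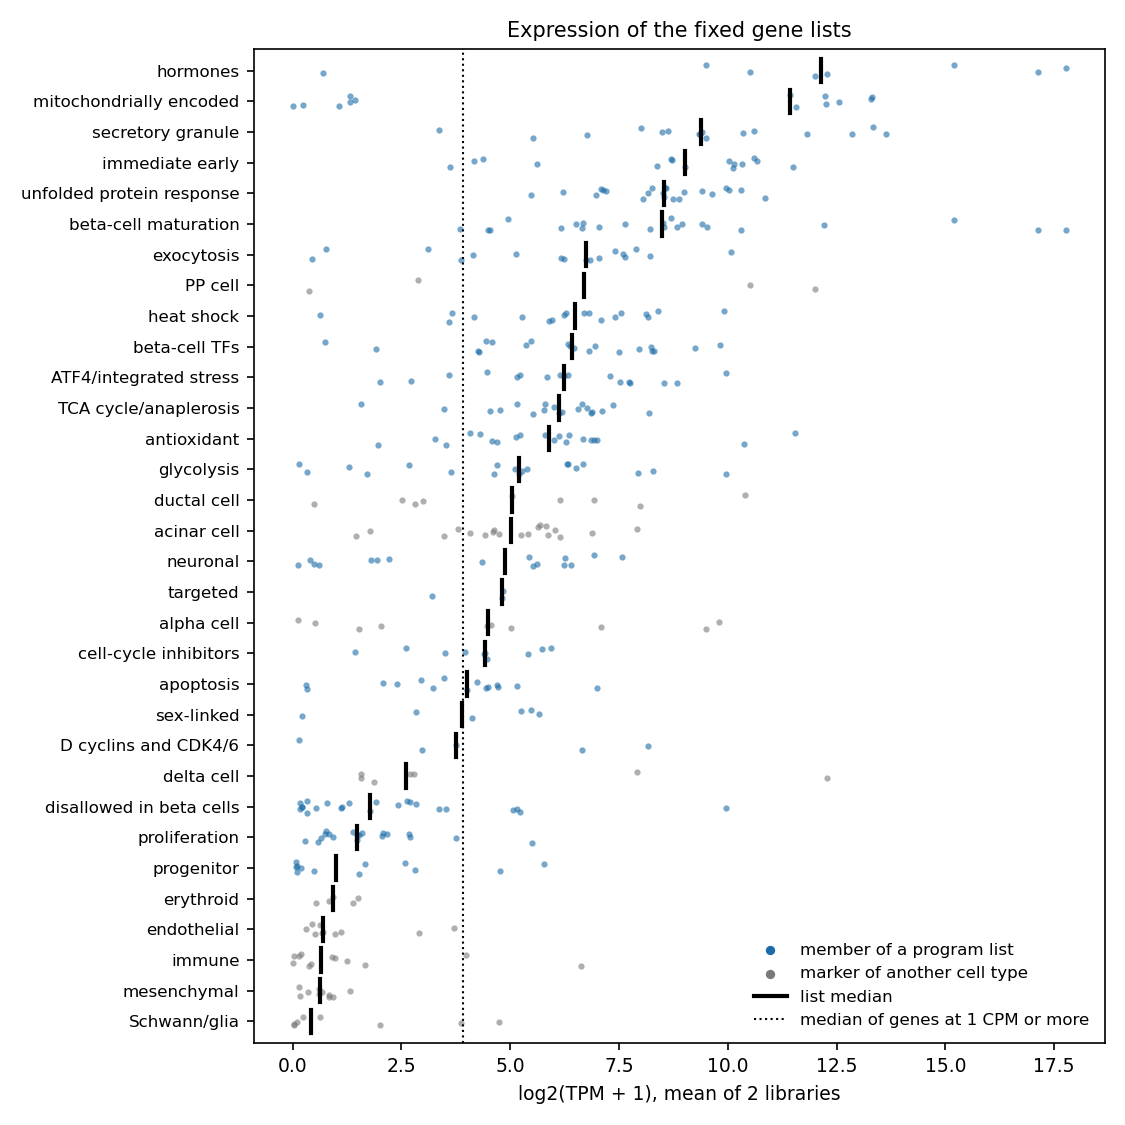
Expression of the members of each fixed gene list as log2(TPM + 1), the mean of the 2 mutant libraries, with list medians as black bars and the median of the 13955 genes at 1 CPM or more (log2 value 3.91) as a dotted line. Hormone, mitochondrially encoded, granule and immediate-early lists lie farthest to the right, and lists of endothelial, immune, mesenchymal and Schwann or glial markers farthest to the left.

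Markers of the other islet and pancreatic cell types were present at different levels. Of 94 markers, 59 were detected in both libraries. Alpha-cell markers (8 of 10 detected, percentile 81.47) summed to 1429 and 1196 CPM, mostly Slc7a2 with 451 ± 15.6 CPM, Gcg, and Ttr with 386.5 ± 55.3 CPM (SD, n = 2). Delta-cell markers (7 of 7, percentile 7.78, or 1.52 in library 1 alone and 0.17 with detection at 5 CPM) summed to 1671 and 1262 CPM, mostly Sst, with Rbp4 at 118 ± 9.095 CPM, Lepr at 15.1 ± 11.6 CPM and Ghsr lowest by TPM at 3.18 ± 0.291 CPM. PP-cell markers (3 of 4, percentile 99.77, or 76.99 without length scaling) summed to 979 and 1215 CPM, with Tspan8 at 3.98 ± 0.0671 CPM. Ductal markers (8 of 9, percentile 93.93) were led by TPM by Spp1 at 813 ± 217 CPM, Epcam at 202.5 ± 13.8 CPM and Ambp at 61.7 ± 17.2 CPM, while the duct keratin Krt19 was at 3.20 ± 1.45 CPM. Acinar markers (17 of 19, percentile 98.60) summed to 165.5 CPM in library 1 and 742 CPM in library 2. Their percentile was 52.62 in library 1 and 100 in library 2, and it was 13.84 without length scaling and 92.31 with detection at 5 CPM.

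Non-epithelial cell markers were scarce, and where few of them were detected the percentile is low by construction. Endothelial markers (6 of 10 detected, percentile 0) summed to 32.0 and 23.6 CPM, led by Esam at 12.6 ± 2.94 CPM and Plvap at 4.68 ± 1.54 CPM (SD, n = 2), with Eng at 1.71 ± 0.682 CPM and Flt1 the lowest detected by TPM at 2.097 ± 0.370 CPM. Mesenchymal markers (5 of 10, percentile 0) summed to 17.1 and 11.4 CPM, with Col3a1, Rgs5 and Col1a1 between 2.18 and 2.86 CPM in the mean and Col1a2 the lowest detected by TPM. Immune markers (2 of 12, percentile 0) summed to 55.5 and 45.5 CPM, of which C1qa had 37.2 ± 2.66 CPM and Cd74 had 9.05 ± 2.498 CPM. The leukocyte gene Ptprc had 0.878 and 0.487 CPM. Schwann and glial markers (3 of 8, percentile 0) summed to 46.6 and 40.7 CPM, with Ngfr at 17.1 ± 4.98 CPM. Erythroid markers (0 of 5, percentile 0.04) summed to 1.34 and 2.67 CPM. The globin genes share over 50% of their words with one another and are uncertain singly. Detection at 5 CPM left 38 of the 94 markers.

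Between the libraries, the largest ratios involved Xist and a few single genes. Xist, the RNA that coats the inactive X chromosome of female cells, had 5.01 CPM in library 1 and 653 CPM in library 2, a log2 ratio of 7.02. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were present in both libraries and stood at 102, 74.4, 70.4 and 46.4 CPM in library 1 against 64.2, 42.6, 41.7 and 21.4 CPM in library 2. Among genes with a mean of 10 CPM or more, the largest ratios towards library 2 were those of A730046J19Rik (0.140 and 42.6 CPM), Gm4841 (0.359 and 52.1 CPM), Xist, F830016B08Rik (0.678 and 37.9 CPM) and Gbp2 (1.54 and 26.6 CPM), a guanylate-binding protein induced by interferon. The largest towards library 1 were those of Gm48837 (101 and 0.923 CPM), Ankrd55 (27.5 and 0.718 CPM), the tight-junction gene Cldn11 (39.2 and 2.49 CPM), the prostaglandin receptor Ptger3 (265.5 and 37.4 CPM) and the pseudogene Rpsa-ps10 (22.2 and 6.10 CPM). Rpsa-ps10 shares 82.3% of its words with Rpsa and its other copies, so its count is uncertain. Xist lies on chromosome X from 103460366 to 103483254, and its transcripts overlap those of the antisense gene Tsix over part of their length. A730046J19Rik lies on the same chromosome from 144153695 to 144166274. Gm48837 lies on chromosome 13 from 112356925 to 112367845, antisense within Ankrd55 (112288451 to 112384002). Their exons overlap over 5.7% of Gm48837, so reads there cannot be assigned to either gene.

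Agreement between the libraries was measured over 20681 genes. The chi-square statistic against counting error alone was 592112 on 20680 degrees of freedom, or 28.6 per degree of freedom, and the biological coefficient of variation from edgeR was 18.44%. Across genes, Pearson's r of log2(CPM + 1) was 0.9931 and Spearman's rho was 0.9828. The exact binomial test called 845 of the 20681 genes, of which 378 were higher in library 2 and 467 in library 1. Among the 9286 tested genes with a mean of 10 CPM or more, 96 were called, 64 higher in library 2 and 32 in library 1. This test covers counting error only. With the common dispersion of the libraries taken into account, an alternative chosen after seeing the data, 206 genes remained, all among the 845.

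**Figure D3:**
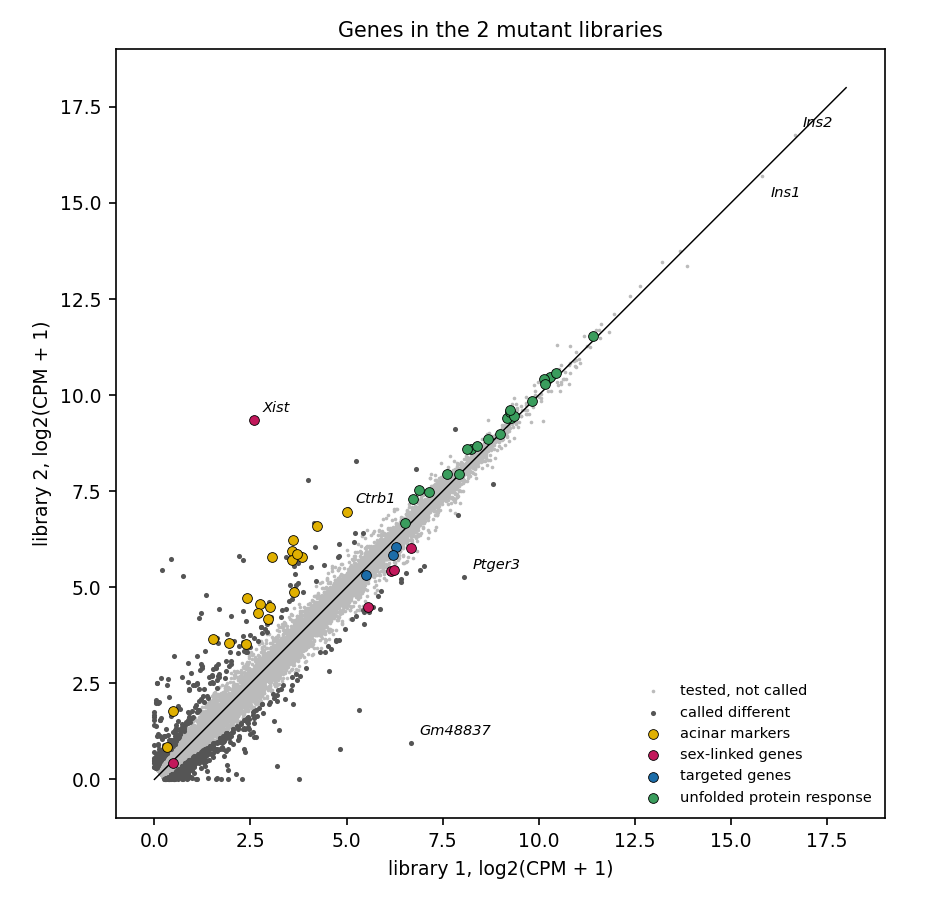
Expression of the 20681 tested genes in library 2 against library 1 of mutant beta cells, each as log2(CPM + 1), with the 845 called genes in dark grey, 4 fixed lists in colour and the diagonal as a line. All 19 acinar markers and Xist lie above the diagonal, and 21 of 22 genes of the unfolded protein response lie slightly above it.

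Acinar enzymes and genes of the unfolded protein and ATF4 responses were shifted towards library 2. All 19 acinar markers were called higher in library 2, with a median log2 ratio of 2.02 at percentile 100 of matched random lists. Chymotrypsinogen (Ctrb1) had 31.2 and 124 CPM, pancreatic lipase (Pnlip) 17.9 and 95.04 CPM, and trypsinogen (Prss2) 12.2 and 57.6 CPM. Trypsinogen copies Try4, Try5 and Prss3 share 47.6% or more of their words and are uncertain. With the common dispersion, 15 of the 19 remained called. Of 22 genes of the unfolded protein response, 21 had higher values in library 2, with a median log2 ratio of 0.22 at percentile 100, and none reached 2-fold. The ATF4 response list had a median of 0.18 (percentile 99.99), with 13 of 17 values higher in library 2 and 0 called. The TCA cycle list had a median of 0.08 (percentile 98.73), and ductal markers had 0.23 (percentile 99.48), in both with 0 called. Proliferation genes had a median of 0.13 (percentile 97.68), with Bub1b called, at 0.539 and 1.23 CPM, and the percentile was 96.18 with a minimum of 100 reads. Progenitor genes had a median of 0.29 (percentile 98.88), which turned to −0.50 with a minimum of 100 reads. In that list Neurog3 was called higher in library 1, with 21.9 and 10.1 CPM.

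Several lists were shifted towards library 1. Of 20 beta-cell transcription factors, 18 had lower values in library 2, with a median log2 ratio of −0.17 at percentile 0.02 and 0 called. Mafa, at 810 and 995 CPM, and Nkx6-1, at 668 and 724 CPM, were the exceptions. The targeted genes had a median of −0.25 (percentile 2.21), granule genes −0.11 (percentile 2.13) and disallowed genes −0.26 (percentile 1.42), of which Pdgfra alone was called, with 0.678 and 0.256 CPM. Sex-linked genes had a median of −0.71 (percentile 0), with Xist called higher in library 2 and Kdm5d called higher in library 1. Endothelial markers had a median of −0.58 (percentile 0.17), with Pecam1 called. Immune markers had a median of −0.70 (percentile 0.18), with Cd79a and Lyz2 called, and percentile 4.82 with a minimum of 100 reads. In total, 14 of the 32 lists lay outside the central 95% of random lists, where chance would give 1.6.

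The remaining lists lay within the central range. Their median log2 ratios and percentiles were −0.08 and 18.62 for hormones, 0.07 and 95.98 for beta-cell maturation, −0.07 and 14.05 for exocytosis, −0.01 and 56.20 for heat shock, 0.04 and 90.02 for antioxidant genes, and 0.00 and 58.38 for immediate-early genes. They were −0.05 and 39.70 for cell-cycle inhibitors, 0.06 and 78.36 for D cyclins, −0.12 and 5.44 for neuronal genes, −0.10 and 8.09 for glycolysis, 0.16 and 97.28 for mitochondrially encoded genes, and −0.14 and 5.06 for apoptosis. For cell markers they were −0.09 and 26.54 for alpha cells (−0.21 and 1.78, outside the range, with a minimum of 100 reads), −0.09 and 29.70 for delta cells, 0.20 and 93.80 for PP cells, −0.39 and 6.03 for mesenchymal cells, −0.12 and 38.80 for Schwann or glial cells, and 0.36 and 89.99 for erythroid cells. Members were called in 7 of them. Higher in library 2 were Cdkn1a, an inhibitor of cyclin-dependent kinases (35.9 and 72.0 CPM), the phosphofructokinase Pfkp (6.66 and 15.6 CPM), the leptin receptor gene Lepr (6.92 and 23.4 CPM), Alas2 and Hbb-bs. Higher in library 1 were, among others, Stmn2, Col1a2 and Pdgfra. Adjusted over the list alone, the number of members called at 2-fold was the same in all 32 lists. With the common dispersion, which was estimated from the same 2 libraries, of the called list members outside the acinar list only Xist and Lepr remained.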

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

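The edgeR negative binomial test with the common dispersion was chosen only after the result was seen; the other alternatives were planned. No paired analysis was possible because the series as analysed here holds 1 group. Without a minimum ratio, 6606 genes were called different between the libraries, 2733 higher in library 2 and 3873 in library 1. With the common dispersion the numbers were 206, 132 and 74, because that test adds the spread between the libraries to the counting error. TMM, DESeq2 size factors, totals without the 10 highest genes and no filter called 840, 837, 842 and 770 genes, of which 809, 806, 840 and 753 were among the 845. Totals without the 10 highest genes raised every CPM by construction, to 92.0 for Myt1, 53.7 for Myt1l, 83.1 for St18, 509 for Gcg, 1682 for Sst, 972 for Ppy and 434 for Pyy. Detection at 5 CPM left 38 markers of other cell types. With a minimum of 100 reads, the progenitor list turned to a median log2 ratio of −0.50, since only 5 of its 8 tested genes were left, and alpha-cell markers moved below the central range, at −0.21 (percentile 1.78). Without length scaling, the mean log2 ratio turned to −0.32 for Pcsk1 over Pcsk2 and to 0.15 for Myt1 over St18. The latter pair was called only there; leaving out either library gave −0.059 to 0.058 with length scaling, and it was not called. The placing of the neuronal, acinar, glycolysis and PP-cell lists against the upper bound of the central 95% of random lists changed under at least 1 alternative. Against the lower bound only that of the delta-cell list changed, from percentile 7.78 to 1.52 in library 1 alone and 0.17 with detection at 5 CPM. Depth limits genes near 0.0599 CPM in library 1 and 0.0769 CPM in library 2.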

Other observations

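The tests of library scaling, insulin levels, immune markers, chromosomes and the distance between nuclear copies were chosen only after the result was seen, and the 5 genes without mt-Atp8 were set apart after it was seen too. Genes induced by interferon were higher in library 2 as a group. In a list of 15 such genes compiled from the called genes, Iigp1, an interferon-inducible GTPase, had 15.04 CPM in library 1 and 220 CPM in library 2, Gbp4 had 31.8 and 129 CPM, and Igtp had 9.74 and 54.5 CPM. A list of 25 genes induced by interferon gamma was then written without sight of their values. All 24 that could be tested had higher values in library 2, 12 were called (23 passed when adjusted over the list alone, at any ratio), and 8 passed with the common dispersion. Among the 12, Tap1, which loads peptides for antigen presentation, had 20.2 and 46.4 CPM, B2m had 41.8 and 84.4 CPM, Nlrc5 had 2.73 and 12.8 CPM and Zbp1 had 0.658 and 5.31 CPM. In a list of 18 genes tied to type I interferon, also written without sight of their values, 17 had higher values in library 2 and 5 were called, among them Irf7 (2.93 and 8.92 CPM) and Rtp4 (2.015 and 6.69 CPM). Of the 18, 3 passed with the common dispersion, and the median log2 ratio of the list was 0.63, at percentile 100. Gbp6, Gbp10, Tgtp1, Tgtp2, Ifit3 and Oas1a share over 50% of their 50-base words with other genes and are uncertain singly.

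The first pattern is the difference in Xist (log2 ratio 7.02) and in the Y-linked genes, whose median log2 ratio was −0.78 with a range of −1.12 to −0.67. Scaling or depth is argued against by the shift of the alternative scalings, at most 0.044 on the log2 scale. Cells of another type from other mice are argued against by the summed insulin reads, which changed by 0.03 and not by the amount of the Y-linked genes. Different shares of female and male beta cells in the 2 pools may account for the pattern. Xist was higher and all 4 Y-linked genes were lower in library 2, the directions that a larger share of female cells would give. The explanation stays open, since 7 genes that escape X inactivation had a median log2 ratio of 0.13, with 5 of them higher in library 2. This lay above 0 but at percentile 95.64, short of the upper bound of the central 95% set beforehand, so that test could not decide. The label gives pooled sexes for both libraries, and Xist in library 1 was 5.01 CPM.

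The second pattern is the interferon-inducible group. More immune cells as the whole cause are argued against by the fixed immune markers, of which 0 of 10 tested were higher in library 2 (median log2 ratio −0.70), while the summed reads of the 10 of 12 markers with under 100 reads changed by −0.95 (95% upper bound −0.15, with the common dispersion), below the median of 1.0 of the 25 genes. The immune test took 4 forms after the result was seen. With a minimum of 100 reads, only C1qa and Cd74 remained, and their median left the question open (−0.36, percentile 4.82). Their summed reads changed by −0.23, with a 95% upper bound of 0.51 that also lies below 1.0. Of the 2, C1qa, with 1958 and 1377 reads against 21 and 11 of its partner C1qb, hardly measures immune cells. A sequence or copy-number difference in the genes of 1 locus is argued against for the group. An example would be the cluster on chromosome 18 that holds Gm4841, F830016B08Rik and Iigp1. The 32 called genes lie on 12 chromosomes, 31 of them outside chromosome 18. They include the 15 compiled from the called genes, but the 12 called of the 25 genes alone lie on 6 chromosomes. A single locus that acts on genes elsewhere was not tested and stays open. An interferon response in the mice or cells of library 2 could account for the group. The median of the 25 genes (log2 ratio 1.0) lay at percentile 100 of matched random lists. What differed between the pools, such as sex, housing or infection, was not tested. A rare type such as T cells (Cd3e, 2 and 1 reads) was not tested either, in cells that had been sorted as beta cells. The share of acinar cells, whose 19 markers were all called higher in library 2 (median log2 ratio 2.02), was not tested as a source.

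The third pattern is that 5 mitochondrial genes, mt-Nd3, mt-Nd4l, mt-Co2, mt-Co3 and mt-Atp6, had at most 0.429 CPM in the mean while 7 others had 932 CPM or more. Each of the 5 shares at least 98.0% of its words with other genes, chiefly copies on chromosome 1, so reads matching several places may have been left uncounted. This stays open because mt-Co1 and mt-Nd4, which were abundant, share 51.1% and 62.2%, above the bound of 50 set beforehand. That miss does not speak against uncounted reads, since 48.9% and 37.8% of their words are unique and could still be counted. The 1 low gene with unique annotated words, mt-Atp8, shares 0%, against the bound of 90, which leaves low abundance open too. It has only 204 bases, of which 21.1% overlap mt-Atp6 on the same strand, so its count is uncertain. The search for shared words covered only annotated transcripts. On the mitochondrial genome, mt-Atp8 lies between mt-Co2 and mt-Atp6. Their copies on chromosome 1 (GRCm38) start 914 bases apart along the minus strand, the same distance as on the mitochondrial genome. An unannotated copy of mt-Atp8 may therefore lie between them, which needs the genome sequence to check.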
